A study of Rattus norvegicus with 19 samples.

How the data were processed

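RNA from 6 normal mammary glands and 13 mammary carcinomas of female rats, all F1 hybrids of the Sprague-Dawley and Copenhagen strains, was measured on 19 Agilent single-colour (Cy3) arrays, 1 array per sample. Per the labels, RNA was purified with a kit that also yields DNA, amplified and labelled with a low-input kit, and scanned images were read with Agilent Feature Extraction 10.7.3.1. Per the file headers, the scanner files give each spot's intensity after background subtraction and spatial detrending, median pixel intensities of the spot and its surroundings, and flags for spots that are well above background, saturated or uneven. The authors also deposited a table on the log2 scale, with each array set to 0 at its own 75th percentile. Checked against the scanner files, its columns followed the log2 scanner intensities with a Pearson correlation of at least 0.998 across probes. A constant shift of 0.43 to 0.54 separated the scalings, and the largest SD of the difference was 0.21. The labels do not state the scaling step, which was read from the values.

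Values for the comparisons came from the background-subtracted intensities. Control spots were removed, leaving 58717 spots and 30367 probes. Between 403 and 1069 spots per array were marked by the scanner software as uneven or as deviating from their replicate spots, and these were treated as missing. No spot was saturated. The log2 intensity was reduced by the array's 75th percentile, and spots of a probe were averaged. Probes were matched to gene symbols through the RefSeq accession in the array annotation, without its version, and a current rat gene table. This gave 18005 probes for 15168 symbols, and 12362 probes without a symbol were kept out of the main comparison. Genome positions were not used, since the array annotation and the gene table rest on different rat assemblies. A probe was counted as well above background on an array when at least 0.5 of its spots were, and was kept when this held on at least 6 arrays. Where a gene had several such probes, the probe with the highest mean over all arrays was used, and 2112 genes had more than 1. For 7 genes, different probes passed the test in opposite directions. This left 12789 genes, of which 86 lacked a value on some arrays.

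Differences were tested with limma 3.58.1 in R 4.3.3, by a linear model with group as the only term and moderated variances that follow mean intensity, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists were tested with camera from limma, with the correlation between genes estimated from the data, and adjusted over 32 lists. The lists were written before the data were examined and hold 836 entries, of which 653 different genes were tested. They cover adipocytes, brown adipocytes, luminal, basal and lactating epithelium, fibroblasts, endothelium, macrophages, T and NK cells, B and plasma cells, lymph node stroma, mast cells, neutrophils, skeletal muscle, Schwann cells and red blood cells. The others cover the cell cycle, oestrogen receptor response, the HOX clusters, other developmental transcription factors, Polycomb and DNA methylation enzymes, p53 targets, homologous recombination, epithelial-mesenchymal transition, glycolysis and hypoxia, fatty acid synthesis and oxidation, cholesterol synthesis, interferon response, Wnt antagonists and targets, receptor kinases and oncogenes, and the unfolded protein response. Many of their genes are expressed by more than 1 cell type of the gland, and some genes stand in several lists. An array's list score is the mean of the list's genes, each centred on its mean. Spread within groups was the root mean square distance of an array from its group's mean over the 12703 genes with a value on every array, corrected for group size. It was compared by a 2-sided exact permutation test over 27132 splits. Correlations between list scores used the 13 carcinomas, 10 pairs written before the data were examined, and 100000 permutations, or all orders where fewer than 10 carcinomas were used.

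Genes named in the text followed a rule written before the data were examined. In each direction the rule took the 8 largest changes among genes past the threshold whose carcinoma values all lay on the same side of all normal gland values. It added up to 3 genes per direction that were well above background on every array of a group and on none of the other, with the fold given as a lower bound. Such a bound allows for values near background under the background subtraction used, and not for sampling error or another background correction. From each list it took the 2 largest changes past the threshold in the list's more frequent direction, and further examples came from the 4 largest changes of the list. Esr1, Pgr, Erbb2, Mki67, Ezh2, Dnmt1, Cdkn1a, Brca1 and Brca2 were among those always to be named. Mki67 and Dnmt1 had no probe past the filter with a symbol and were not analysed here. The rule gave 78 genes, of which some are not reported here.

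The number of arrays limits the precision of each value. On data simulated with each gene's observed spread and independent genes, 50 genes were changed at each fold: 6% of genes changed 1.5-fold passed, 40% of those changed 2-fold, 80% of those changed 4-fold and 100% of those changed 8-fold. Far fewer genes were changed there than the 2936 that passed in the data, so the adjusted threshold required smaller p values. These shares therefore do not give the share of such changes found in the data. Of 12455 unchanged genes 6 passed, and of 2 lists simulated as moved 2 were called, with 0 others. As the simulated genes were independent, this does not show how readily camera calls a list whose genes move together. In the data the estimated correlation was 0.49 for macrophages and 0.72 for the cell cycle, so a list that camera did not call need not be unchanged.

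Alternatives written before the data were examined were normexp background correction with an offset of 50, quantile normalization, scaling by 2 kinds of median, the authors' values, no filter or a stricter filter on dim probes, the mean of a gene's probes, and keeping the marked spots. Others were variances without an intensity trend, array weights, blocks for slide, scan day or sample number, luminal or adipocyte scores as covariates, camera with a preset correlation of 0.01, fry, and leaving out each array. The block for sample number left out carcinomas 7 to 13, whose numbers no normal gland shared. The normexp correction used median pixel intensities, where mean intensities had been planned. Alternatives chosen after the data were seen were fits within each slide and within the first scan day, a block for the code series described in the report, fits of either code series alone, fits without the 3 arrays that the scanner software marked for evaluation, and array brightness as a covariate. Fits of these subsets kept the genes of the main comparison. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Probes without a symbol were tested only as a group, and no array was left out of the main comparison.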

Results

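Gene expression was measured in 6 normal mammary glands and 13 mammary carcinomas from female rats, with 1 array per sample. The labels describe the carcinomas as induced by radiation. Rats were untreated or received 4 Gy of gamma rays to the whole body at 7 weeks of age, and the labels do not say which normal glands came from irradiated rats. The comparison is therefore of tumour with gland and does not isolate an effect of irradiation. Carcinoma arrays were brighter: the 75th percentile of the intensity was 295.5 to 673 on normal gland arrays and 485 to 1428 on carcinoma arrays. The share of spots well above background was 65.5 to 77.2% (median 66.7%) in normal glands and 62.3 to 84.2% (median 80.3%) in carcinomas. Pearson correlations across genes, which are not independent replicates, were 0.922 to 0.978 between normal glands, 0.885 to 0.959 between carcinomas and 0.853 to 0.937 between groups. The arrays lay on 3 slides that each held both groups, with 3 normal glands and 4 carcinomas, 2 and 4, and 1 and 5. Slide 2 was scanned on another day than slides 1 and 3.

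**Figure D1:**
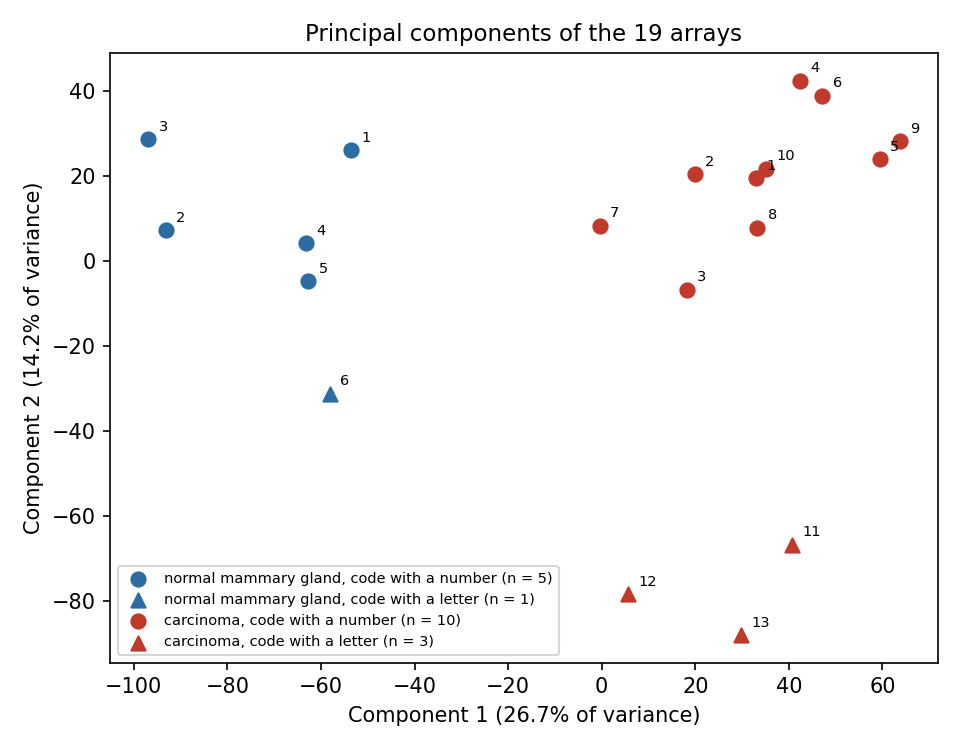
Positions of the 19 arrays on the first and second principal components of normalised log2 expression, which hold 26.7% and 14.2% of the variance; each point is an array, numbered by replicate, coloured by group and shaped by the kind of sample code. The 6 normal glands lie at -53.6 or below on the first component, and the 4 samples coded with a letter lie at -31.3 or below on the second.

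Samples also differed by the codes in their descriptions, a split noticed after the data were seen. Normal gland 6 and carcinomas 11, 12 and 13 carried a letter code, and the other 15 samples a number. The 4 letter-coded samples lay at -31.3 to -88.0 on the second component, and all number-coded samples at -6.80 or above. Letter-coded samples shared slide 3 with carcinomas 8 and 10, which carry numbers.

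The comparison of carcinoma with normal gland asked how gene expression in radiation-induced mammary tumours differs from that of the gland. Of 12789 genes tested, 1244 were higher in carcinomas, 1692 were lower and 9853 did not pass the limma test. Thus 23.0% of all genes tested passed, the share against which the list counts below are to be read. At least 2-fold changes numbered 512 among the higher genes and 1158 among the lower. Values in parentheses after gene names are log2 changes, carcinoma minus normal gland, ± SE, with n = 13 carcinomas and 6 normal glands. Among the largest rises with all carcinomas above all normal glands were those in the phosphatase gene Ptpn13 (2.52 ± 0.42), the spindle gene Aspm (2.40 ± 0.42), the kinetochore gene Cenpf (2.04 ± 0.40) and the actin-binding gene Mtss1 (1.89 ± 0.31). Others were Nfat5 (1.69), a transcription factor of the osmotic response, Sqle (1.66), an enzyme of sterol synthesis, and the zinc finger gene Zmym3 (1.64). The largest falls were in Adipoq (-10.26 ± 0.67), which encodes adiponectin, and in the retinol carrier Rbp4 (-9.84 ± 0.54), the carboxylesterase Ces1d (-9.38 ± 0.85) and the hormone resistin, Retn (-8.55 ± 0.41). Car3 (-7.90), Cyp2e1 (-7.78), Fabp4 (-7.71) and Pck1 (-7.48) came next, all genes of fat cell or liver metabolism. Several of these sizes rest in part on values near background: Adipoq was well above background on 8 of 13 carcinoma arrays, Rbp4 on 7, Ces1d on 6, Car3 on 9, Cyp2e1 on 1 and Pck1 on 6, and Aspm, Cenpf and Zmym3 on 5, 4 and 4 of 6 normal gland arrays. Adjusted p was at most 0.00136 for these 7 rises and at most 1.8e-07 for these 8 falls.

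Fgl1, a secreted fibrinogen-like protein gene, was well above background on all 13 carcinoma arrays and on 0 normal gland arrays, and was at least 7.00-fold higher (adjusted p = 0.00307). Gtse1, a cell cycle gene, was at least 3.61-fold higher (adjusted p = 9.45e-05), while its change turned to -0.13 with normexp background correction. Slc36a2, an amino acid transporter gene, was well above background on all 6 normal gland arrays and on 0 carcinoma arrays, and was at least 40.1-fold lower (adjusted p = 2.56e-09). Fgl1 (0.53), Cenpf (0.35) and Zmym3 (0.20) did not pass with normexp. The changes of Fgl1 and Gtse1 there lay below their bounds, which hold only for the background subtraction used. A further probe of Nfat5 gave 0.82 and did not pass (adjusted p over probes 0.0777).

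The counts of changed genes depended on single normal glands and on the model. Without normal gland 2 they were 697 higher and 1120 lower, and without normal gland 3 they were 665 and 1084. Within slide 1 the counts were 153 higher and 534 lower, within slide 2 they were 45 and 267, and within slide 3, with 1 normal gland, 0 and 31. At an unadjusted p under 0.05, limma gave 1154 genes on slide 3. With slide as a block they were 1402 and 1798, with scan day 1366 and 1823, and with the code series 1596 and 1903. The first scan day alone gave 673 and 1160. The 15 number-coded samples gave 1631 and 1772, and the 4 letter-coded ones, with 1 normal gland, gave 0 and 0 by limma, with 1340 genes at an unadjusted p under 0.05. With normexp correction the median change of all genes was -0.37, against 0.01 in the comparison above, and the counts were 928 higher and 5256 lower. A luminal epithelium score as a covariate gave 755 and 1098, and array brightness gave 11 and 174. An adipocyte score, which held 97.3% of its variance between the groups, gave 0 and 0 by limma. At an unadjusted p under 0.05 it left 523 of 12766 genes, fewer than chance alone gives on average.

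Fat cell genes were lower in carcinomas. Of 23 measured genes of the adipocyte list, 22 fell, 0 rose and 1 did not pass, and 23 fell when adjusted over the list alone. The list's median change was -4.47 and camera called it lower (adjusted p = 2.86e-05 with an estimated correlation). Its median was -4.79, -3.97 and -5.27 within slides 1, 2 and 3, and no carcinoma reached the range of the normal glands. Of 23 fatty acid oxidation genes, 7 fell and 0 rose (8 fell adjusted over the list alone), among them the acyl-CoA synthetase Acsl1 (-2.70 ± 0.83), the carnitine transferase Cpt1b (-1.38 ± 0.37) and Decr1 (-1.15 ± 0.29). Of 17 genes of fatty acid and triglyceride synthesis, 5 fell and 2 rose (6 and 2 adjusted over the list alone). Thrsp (-3.04 ± 0.82) and malic enzyme, Me1 (-1.50 ± 0.46), fell, while the desaturase Scd2 (2.50 ± 0.48) and the elongase Elovl6 (2.00 ± 0.58) rose. Of 21 cholesterol synthesis genes 5 rose, 0 fell and 16 did not pass (9 rose and 0 fell adjusted over the list alone), including Sqle (1.66 ± 0.32), which encodes squalene epoxidase. Of 8 brown adipocyte genes, 2 fell and 6 did not pass (2 fell adjusted over the list alone): the potassium channel gene Kcnk3 (-3.73 ± 0.44) and Cpt1b. The median of that list was 0.36, its mean -0.42 and camera's direction was lower, and the median was -0.67 with normexp and -0.38 without a filter on dim probes.

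Camera called none of these lists apart from the adipocyte list: adjusted p with an estimated correlation was 0.267 for fatty acid oxidation, 0.306 for fatty acid synthesis, 0.269 for cholesterol synthesis and 0.737 for brown adipocytes. Me1 did not pass without normal gland 2 (adjusted p = 0.0779) or with quantile normalization, a further Me1 probe gave -1.20 without passing, and Acsl1 did not pass without normal gland 2 (0.0567) or 4 (0.0538). With the luminal epithelium score as a covariate Thrsp (-2.90 ± 0.97), Acsl1 (-2.61 ± 0.99), Cpt1b (-1.26 ± 0.44) and Me1 (-1.07 ± 0.51) did not pass (adjusted p 0.0503 to 0.165), with larger SEs and, apart from Me1, sizes of at least 91.4% of those without it. With normexp 9 genes of fatty acid synthesis fell, and 7 brown adipocyte genes fell. The falls in fatty acid synthesis numbered 3 without normal gland 1, 2 without normal gland 2 and 3 without normal gland 3, and cholesterol synthesis rises numbered 8 without normal gland 6 and 10 in number-coded samples alone. With array brightness as a covariate, 15 adipocyte genes fell, 1 fatty acid oxidation gene fell and 0 genes of fatty acid or cholesterol synthesis passed by limma.

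Many vessel, macrophage, lymphocyte and lymph node genes fell in carcinomas, although camera called only the lymph node stroma list among them. Endothelial genes fell in 13 of 17 cases (13 adjusted over the list alone), including the junction gene Cldn5 (-3.24 ± 0.68), the lymphatic marker Lyve1 (-3.02 ± 0.47) and Pecam1 (-2.33 ± 0.26). Macrophage genes fell in 17 of 23 cases (21 adjusted over the list alone), with osteopontin, Spp1 (-3.33 ± 0.84), and the scavenger receptor Cd163 (-3.20 ± 0.50) as examples. Of 23 T and NK cell genes 14 fell (18 adjusted over the list alone), such as the receptor gene Klrd1 (-2.66 ± 0.45) and the chemokine Ccl5 (-2.33 ± 0.48). Of 13 B and plasma cell genes 9 fell (10 adjusted over the list alone), such as Tnfrsf17 (-4.24 ± 0.71) and Pou2af1 (-3.28 ± 0.69). No gene of these 4 lists rose. Of 8 lymph node stroma genes, 5 fell (6 adjusted over the list alone), among them the chemokines Ccl21 (-6.19 ± 0.71) and Ccl19 (-5.79 ± 0.69), and Glycam1 (-6.75 ± 2.00), which is also made by milk-secreting cells. In carcinomas 7 and 11 normalised log2 values were 9.16 and 7.05 for Glycam1 and 8.28 and 4.39 for the milk gene Wap. Ccl21 stood at -2.87 and -6.29 there. In carcinoma 4 Glycam1 was -0.71 with Wap at 5.26. The fall of Glycam1, though counted in this list, is thus not evidence of less lymph node stroma. Red blood cell genes fell in 5 of 7 cases (5 adjusted over the list alone), with the beta globin genes Hbb-b1 (-3.26 ± 0.61) and Hbb (-3.21 ± 0.61), which have near-identical sequences. Of 14 Schwann cell genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone), with myelin basic protein, Mbp (-3.74 ± 0.44), and S100b (-3.53 ± 0.74) among the falls.

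Fewer genes passed in the other cell type lists. Of 12 neutrophil genes 2 fell, Retnlg (-2.08 ± 0.55) and Trem1 (-1.98 ± 0.65), and 10 did not pass (2 fell adjusted over the list alone). Of 24 fibroblast and collagen genes 4 fell, 1 rose and 19 did not pass (6 and 1 adjusted over the list alone), and Pi16 (-3.02 ± 0.53) and the matrix gene Fbln1 (-1.79 ± 0.60) were among the falls. No mast cell gene of 11 and no skeletal muscle gene of 20 passed the limma test, over all genes or adjusted over the list alone. Median changes were 0.36 for mast cells, where camera and fry differed in direction, and -1.34 for skeletal muscle. The skeletal muscle median was 0.01 without normal gland 3. For mast cells it was -0.03 without carcinoma 13 and -0.25 without the arrays marked for evaluation.

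Among these lists camera called lymph node stroma alone (median -2.84, adjusted p = 0.0484 with an estimated correlation), and that call was lost with slide (0.109), scan day (0.0844) or code series (0.087) as a block, in 9 other alternatives, and without single arrays (normal glands 1, 4 or 6, or carcinomas 1, 2, 4, 6, 7, 8, 9, 10, 12 or 13, at 0.0501 to 0.087). Its median was -2.07, -4.66 and -3.08 within slides 1, 2 and 3. Adjusted p with an estimated correlation was 0.141 for endothelium, 0.246 for macrophages, 0.267 for T and NK cells, 0.188 for B and plasma cells, 0.268 for red blood cells, 0.267 for Schwann cells, 0.402 for neutrophils, 0.696 for fibroblasts, 0.991 for mast cells and 0.696 for skeletal muscle. T and NK cell falls numbered 8 without normal gland 2, 8 without normal gland 3 and 9 without normal gland 5. Schwann cell falls numbered 3 without normal gland 3, red blood cell falls 3 of 5 genes tested without normal gland 2, and 3 in number-coded samples alone, and neutrophil falls 5 without carcinoma 13 and 4 without carcinoma 2. Fibroblast falls numbered 2 without normal gland 1, 3 or 5 or without carcinoma 9. Trem1 did not pass without normal gland 2, 3 or 4 (0.074, 0.12 and 0.0584), Fbln1 did not pass without normal gland 1, 2, 3, 4 or 5 or carcinoma 4 or 9 (0.0531 to 0.13) or with quantile normalization (0.0522), and Glycam1 did not pass without normal gland 2 (0.0515). With the luminal score as a covariate Trem1 (-2.01 ± 0.78, adjusted p = 0.087) and Fbln1 (-1.87 ± 0.72, 0.0847) did not pass, with larger SEs and undiminished sizes. Klrd1 was well above background on 2 of 13 carcinoma arrays, Tnfrsf17 on 3, and Ccl19 and Trem1 on 9, so their sizes rest in part on values near background. With normexp 7 neutrophil, 7 fibroblast and 10 Schwann cell genes fell, and 3 skeletal muscle genes fell. Further probes of Mbp (-0.61) and Pou2af1 (-1.23) did not pass. With array brightness as a covariate the falls numbered 3 for endothelium, 1 for macrophages, 0 for T and NK cells, 2 for B and plasma cells and 1 for lymph node stroma.

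Luminal genes rose in part and milk genes fell in part. Of 29 luminal epithelium genes, 7 rose, 0 fell and 22 did not pass (7 and 0 adjusted over the list alone), and Gata3 (1.60 ± 0.47), a luminal transcription factor, and Prom1 (1.43 ± 0.43) were the largest rises. Of 17 basal and myoepithelial genes 1 rose, the laminin gene Lamb3 (1.35 ± 0.39), and 1 fell, Pdpn (-1.32 ± 0.47), with 1 and 0 adjusted over the list alone. Of 20 milk protein and lactation genes 5 fell, 0 rose and 15 did not pass (6 fell adjusted over the list alone). Whey acidic protein, Wap (-5.63 ± 1.75), and Glycam1 (-6.75 ± 2.00) fell, and both varied widely between carcinomas, with SDs of 4.63 and 5.30 against 0.55 and 0.61 in normal glands. Of 18 oestrogen receptor response genes 2 rose, the secreted glycoprotein gene Stc2 (1.89 ± 0.53) and the progesterone receptor, Pgr (1.83 ± 0.64), 1 fell and 15 did not pass (1 rose and 0 fell adjusted over the list alone). The list's median was 0.70 and was -0.04 with normexp, which gave a median of -0.37 over all genes. Esr1, the oestrogen receptor gene itself, was well above background on 8 carcinoma and 0 normal gland arrays and did not pass (adjusted p = 0.276). With normexp Esr1 passed as lower, with a change of -0.73 (adjusted p = 0.0013). As it was well above background on 0 normal gland arrays, that call does not show a fall.

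Camera called none of the 4 epithelial and hormone lists, with adjusted p of 0.268, 0.713, 0.402 and 0.569 in the order given, with an estimated correlation. Medians within slides 1, 2 and 3 were 0.29, 0.48 and 1.20 for luminal genes, -3.46, -1.46 and -1.67 for milk genes, and 0.15, 0.31 and 0.70 for oestrogen response genes. Basal genes gave 0.55, -0.11 and 0.22. Pgr did not pass without normal gland 1, 2, 3, 5 or 6 or carcinoma 1, 3, 4, 6, 8, 9, 11 or 13 (adjusted p 0.0514 to 0.11), with slide as a block, with normexp or in number-coded samples alone, and Stc2 did not pass with normexp. Gata3 did not pass without normal gland 2 (0.0667), Prom1 without normal gland 3 (0.0604) or 5 (0.0537), and Wap without normal gland 2 (0.0595) or 3 (0.0599). Milk gene falls numbered 2 without normal gland 2, 3 without normal gland 3 and 10 without carcinoma 7, and oestrogen response rises numbered 4 without carcinoma 12. With the luminal score as a covariate Pgr (1.02 ± 0.68, adjusted p = 0.329) and Wap (-5.53 ± 2.08, 0.078) did not pass. With normexp 11 milk genes fell, and 4 oestrogen response genes fell and 1 rose. With array brightness as a covariate 0 genes of these lists passed by limma.

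**Figure D2:**
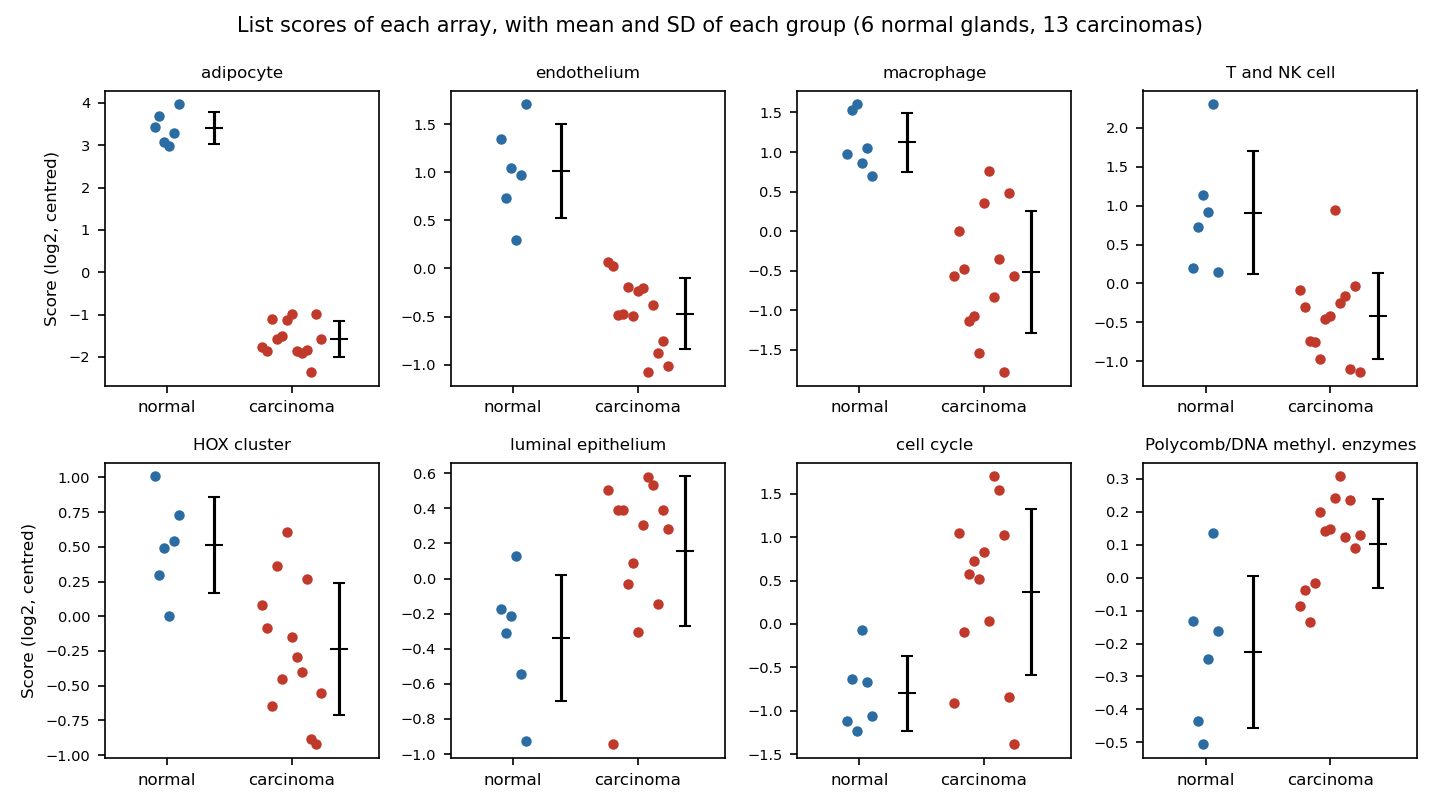
Scores of 8 gene lists, the mean of each list's centred log2 values, for each of 6 normal glands and 13 carcinomas; points are arrays and bars give the group mean and SD. Adipocyte scores were 2.98 to 3.98 in normal glands and -2.37 to -0.98 in carcinomas, while cell cycle scores were -1.23 to -0.07 and -1.39 to 1.71, so that some carcinomas lay among the normal glands.

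Cell division, DNA repair and oncogene lists held more rises than falls, although with normexp DNA repair genes held 3 rises and 5 falls. Over all 12789 genes normexp gave 928 rises and 5256 falls, so these list counts do not show a turn relative to other genes. Of 39 cell cycle genes 17 rose, 0 fell and 22 did not pass (21 and 0 adjusted over the list alone), including the mitotic kinesin Kif11 (2.21 ± 0.51) and the mitotic kinase Pbk (2.12 ± 0.69). Of 27 genes of homologous recombination and DNA repair, 10 rose, 1 fell and 16 did not pass (14 and 1 adjusted over the list alone). Rad50 rose (1.43 ± 0.30), Fancd2 was at least 1.87-fold higher, and Brca2 rose (0.90 ± 0.25), while Brca1 was well above background on 0 normal gland arrays and did not pass (adjusted p = 0.191). That list's median of 0.77 turned to -0.03 with normexp, which lay above the median of -0.37 that normexp gave over all genes. The changes of Rad50 turned to -0.14, Fancd2 to -0.42 and Brca1 to -0.74. Brca1 passed as lower there (adjusted p = 0.0021) and as higher with quantile normalization (0.92, adjusted p = 0.0477), so its direction is not settled. Of 33 receptor kinase and oncogene list members 10 rose, 0 fell and 23 did not pass (12 rose and 1 fell adjusted over the list alone). Mycn was at least 5.42-fold higher, the cell cycle inhibitor gene Cdkn2a rose (2.66 ± 0.55), as did Cdkn2b (2.32 ± 0.47) and the growth factor receptor gene Fgfr2 (1.96 ± 0.64), and the receptor gene Erbb2 rose by less (0.64 ± 0.21). The log2 change of Mycn was 4.91, 0.67 and 3.16 within slides 1, 2 and 3, and carcinoma 9 (-7.31) lay among the normal glands (-7.35 to -5.42). Cdkn2a and Cdkn2b are inhibitors of division rather than oncogenes. Of 24 p53 target genes 4 fell, 2 rose and 18 did not pass (4 and 2 adjusted over the list alone). Both counts lay near the shares over all 12789 genes. The falls included the cell cycle inhibitor Cdkn1a (-1.40 ± 0.29) and Gdf15 (-1.08 ± 0.38), and the rises were Zmat3 (1.21 ± 0.26) and Plk2 (1.00 ± 0.28).

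Camera called none of these lists, with adjusted p of 0.31 for the cell cycle, 0.268 for DNA repair, 0.186 for receptor kinases and oncogenes and 0.631 for p53 targets, with an estimated correlation. Cell cycle medians were 1.10, 1.24 and 1.33 within slides 1, 2 and 3, DNA repair medians 0.75, 0.85 and 0.41, oncogene medians 0.59, 0.57 and 0.47, and p53 target medians -0.04, -0.06 and -0.41. Cell cycle rises numbered 11 without normal gland 3 or 6, and DNA repair rises 5 without normal gland 3. With normexp 11 cell cycle genes rose and 3 fell, 7 oncogene list members rose and 3 fell, and 2 p53 targets rose and 6 fell. With the luminal score as a covariate Pbk (2.12 ± 0.82, adjusted p = 0.0859) and Fancd2 (0.0571) did not pass at undiminished sizes and larger SEs, and Erbb2 (0.43 ± 0.23, 0.217) and Gdf15 (-0.77 ± 0.43, 0.235) did not pass at smaller sizes. Pbk was well above background on 1 and Rad50 on 2 of 6 normal gland arrays. Oncogene list rises numbered 4 without normal gland 2, 5 without normal gland 3, and 6 without normal gland 4, carcinoma 1 or carcinoma 5, or without the 3 arrays marked for evaluation. Pbk did not pass without normal gland 1, 2, 3 or 6 (highest adjusted p = 0.0707), Fancd2 without normal gland 1, 2 or 5 (0.0673), Erbb2 without normal gland 2 or 3 (0.106) or in number-coded samples alone, Brca2 without normal gland 3 (0.0549) and Gdf15 without normal gland 1, 2, 4 or 6 or carcinoma 1, 4, 5, 6, 8, 9 or 11 (0.0525 to 0.122), with quantile normalization (0.0652) or with median scaling over all probes (0.0678). Kif11, Pbk, Mycn, Rad50, Fancd2 and Brca2 did not pass with normexp. The log2 change of Mycn was 0.42 there, below its bound, which holds only for the background subtraction used. A further Cdkn1a probe gave 0.40 and the gene did not pass with the mean of its probes. With array brightness as a covariate 0 genes of these 4 lists passed by limma.

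Developmental transcription factor genes fell more often than they rose. Of 15 HOX genes 4 fell, 0 rose and 11 did not pass (4 fell adjusted over the list alone): Hoxa7 (-3.14 ± 0.48), Hoxb7 (-2.48 ± 0.32), Hoxd9 (-2.06 ± 0.28) and Hoxd10 (-1.22 ± 0.42). Of 54 other developmental transcription factor genes 17 fell, 3 rose and 34 did not pass (17 and 3 adjusted over the list alone). The homeobox gene Gsc (-4.21 ± 0.59), Gata4 (-3.59 ± 0.80) and Osr2 (-2.87 ± 0.60) fell, and the homeobox gene Msx2 rose (2.86 ± 0.91). Of 20 genes for Polycomb and DNA methylation enzymes 6 rose, 1 fell and 13 did not pass (6 and 1 adjusted over the list alone). That list holds enzymes that add silencing marks and enzymes that remove them, and a link to the falls above was not tested. Dnmt3a (1.25 ± 0.39), Kdm6b (1.13 ± 0.34), Cbx6 (1.05 ± 0.22) and Ezh2 (0.79 ± 0.25) rose. Kdm6b encodes an enzyme that removes the Polycomb mark, and the change of Dnmt3a turned to -0.05 with normexp.

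Camera called none of these 3 lists (adjusted p = 0.28, 0.268 and 0.246 with an estimated correlation). Medians within slides 1, 2 and 3 were -0.71, 0.00 and -0.91 for HOX genes, -0.52, -0.45 and -0.37 for the other factors, and 0.42, 0.28 and 0.05 for the enzymes. Enzyme rises numbered 3 without normal gland 2 or 3. Dnmt3a did not pass without normal gland 2 (0.0897) or 6 (0.0641), Kdm6b without normal gland 2 (0.0792) or 3 (0.082) or in number-coded samples alone, and Ezh2 without normal gland 2, 3 or 4 (0.0602, 0.0718 and 0.0604) or with normexp. With the luminal score as a covariate Dnmt3a (1.04 ± 0.46, adjusted p = 0.129) and Kdm6b (0.78 ± 0.37, 0.165) did not pass. Gata4 was well above background on 4 and Osr2 on 8 of 13 carcinoma arrays, and Msx2 on 1 of 6 normal gland arrays. With array brightness as a covariate 2 HOX genes and 1 other factor fell and 0 enzyme genes passed by limma, and with normexp 14 HOX genes and 36 other factors fell, with medians relative to all genes of -0.49 and -0.43, while 4 enzyme genes rose and 2 fell.

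Genes of 5 further pathways were compared in the same way. Of 20 genes of epithelial-mesenchymal transition 7 fell, 0 rose and 13 did not pass (7 fell and 1 rose adjusted over the list alone), with S100a4 (-3.03 ± 0.57), which immune cells also express, and the repressor gene Zeb2 (-2.25 ± 0.40) as examples. Of 15 genes of Wnt antagonists and targets 3 fell and 12 did not pass (4 fell adjusted over the list alone), and the antagonists Sfrp4 (-2.77 ± 0.86) and Frzb (-2.11 ± 0.66) were among them. Of 25 glycolysis and hypoxia genes 3 rose and 1 fell (2 and 1 adjusted over the list alone), with the glucose transporter gene Slc2a1 (1.31 ± 0.42) and Ankrd37 (0.96 ± 0.34) rising and Bnip3 (-1.48 ± 0.42) falling. Of 30 interferon response genes 1 rose, Mx2 (0.94 ± 0.32), and 29 did not pass (0 adjusted over the list alone by limma). Of 21 unfolded protein response genes 4 fell and 17 did not pass (4 fell adjusted over the list alone), including Sdf2l1 (-1.34 ± 0.26) and Ddit3 (-0.85 ± 0.29).

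Camera called none of these lists: adjusted p with an estimated correlation was 0.267, 0.402, 0.631, 0.696 and 0.402 in the order given. Medians were -0.72, -0.29, 0.25, 0.31 and -0.29 over all arrays. The interferon median was -0.19 within slide 2 and -0.06 with normexp, which gave a median of -0.37 over all genes. Frzb did not pass without normal gland 1, 2 or 5 (highest adjusted p = 0.0734), Sfrp4 without normal gland 2 or 3 (0.0922), Slc2a1 without normal gland 1, 2, 3 or 6 (0.0642). Ankrd37 did not pass without normal gland 1, 3, 4, 5 or 6 or carcinoma 2, 3, 5, 6, 10, 12 or 13 (0.0501 to 0.11). Mx2 did not pass without normal gland 1, 2, 3 or 4 or carcinoma 1, 3, 4, 8, 10, 11, 12 or 13 (0.0515 to 0.112), and Ddit3 without normal gland 1, 2, 3 or 6 or carcinoma 1, 4, 5, 6 or 9 (0.0517 to 0.105). Ankrd37 also did not pass with slide as a block (0.0557), with normexp (0.0902), with median scaling over probes well above background (0.056) or with marked spots kept (0.0501), and Ddit3 did not pass with quantile normalization (0.0567) or median scaling over all probes (0.0542). With the luminal score as a covariate Ankrd37 (1.03 ± 0.40, adjusted p = 0.0897), Mx2 (1.05 ± 0.38, 0.0686) and Frzb (-2.00 ± 0.79, 0.0932) did not pass at sizes of at least 94.7% of those without it and with larger SEs, and Ddit3 (-0.66 ± 0.33, 0.19) did not pass at a smaller size. With normexp 11 genes of epithelial-mesenchymal transition, 10 Wnt genes and 7 unfolded protein response genes fell, and 3 interferon genes rose and 3 fell. Unfolded protein response falls numbered 2 without normal gland 1 or 6. With array brightness as a covariate 1 gene of epithelial-mesenchymal transition fell and 0 genes of the other 4 lists passed by limma.

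Further genes belonged to counts of 5 or fewer and were named after their values were seen. Against the direction of their lists, Erbb3 (0.70 ± 0.25) rose in the Schwann cell list and Thy1 (1.40 ± 0.44) in the fibroblast list. Bmi1 (-0.80 ± 0.25) fell among Polycomb genes, the end-joining gene Xrcc6 (-0.49 ± 0.14) among DNA repair genes, and Igfbp4 (-1.09 ± 0.39) among oestrogen response genes. Six4 (1.44 ± 0.34) and Tbx3 (1.74 ± 0.58) rose beside Msx2. Srebf2 (0.91) and Hsd17b7 (1.10) rose among cholesterol synthesis genes, and Hk1 (0.85) rose among glycolysis genes. The remaining falls were Dgat1 (-1.29), Agpat2 (-1.12) and Mlxipl (-0.91) in fatty acid synthesis, Cd34 (-1.73) and Pdgfra (-1.68) among fibroblast genes, and Cxcl13 (-3.81) and Ltb (-1.87) in lymph node stroma. Csn1s2b (-4.94), Cidea (-3.23) and Folr1 (-3.00) fell among milk genes, Alas2 (-2.83), Ahsp (-2.46) and Hemgn (-1.51) among red blood cell genes, Tp53i13 (-0.88) and Fas (-0.77) among p53 targets, Wnt10a (-1.72) among Wnt genes, and Pdia4 (-0.82) and Atf6 (-0.81) in the unfolded protein response.

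**Figure D3:**
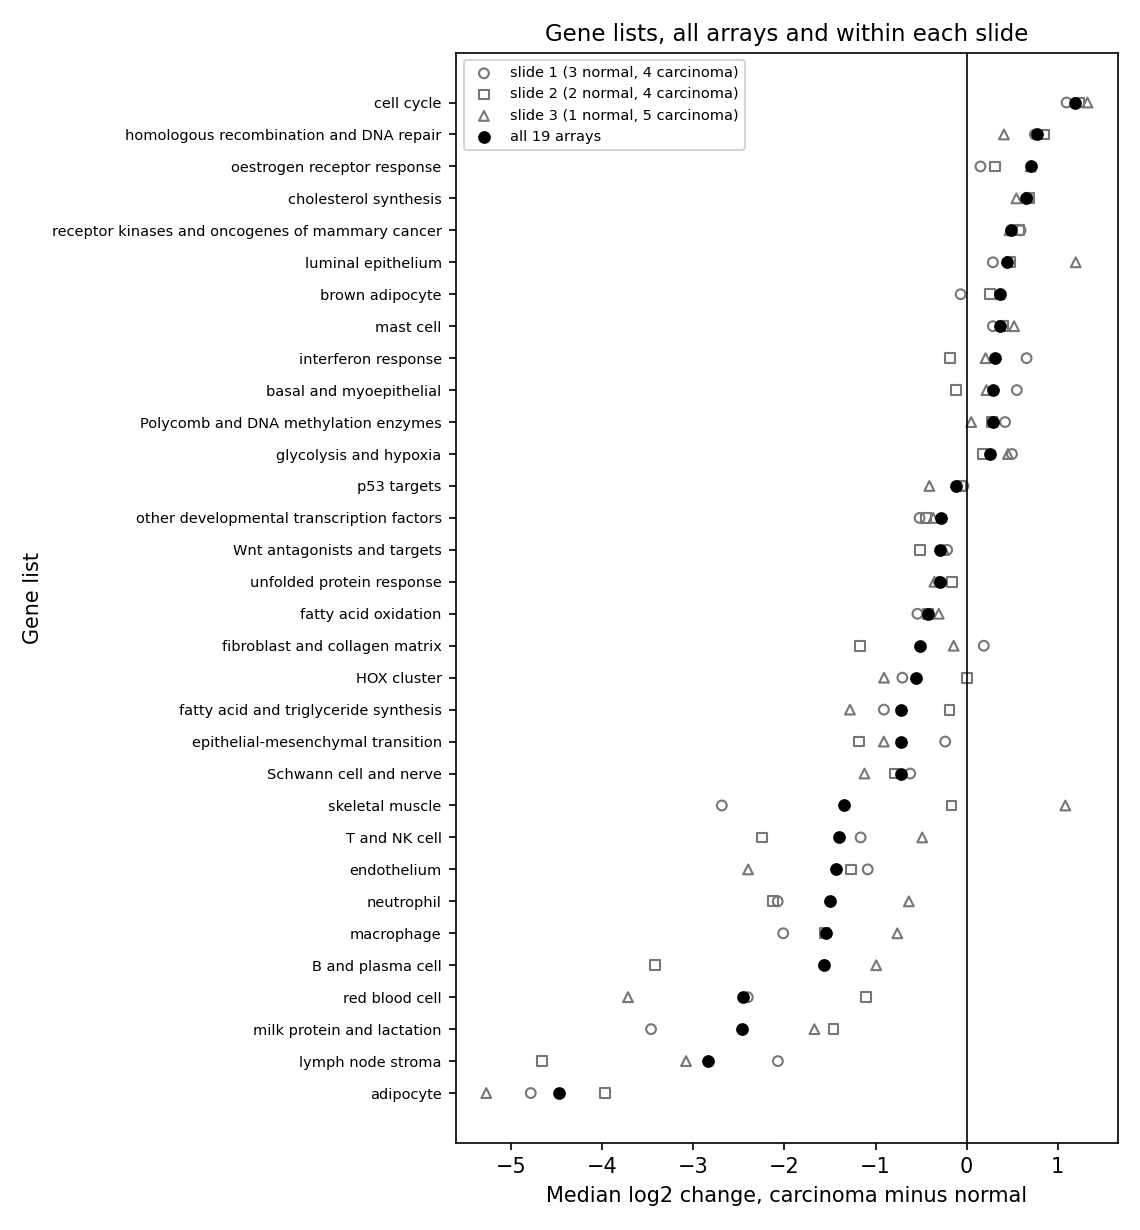
Median log2 change, carcinoma minus normal gland, of each of the 32 gene lists over all 19 arrays (filled points) and within slides 1, 2 and 3 (open circles, squares and triangles). Medians had the same sign on all 3 slides in 26 lists. With normexp background correction the all-array medians of the brown adipocyte, oestrogen receptor response, homologous recombination and interferon lists turned negative. The median of all genes was -0.37 there, and of these lists only brown adipocyte (-0.67) lay below it.

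Taking all 32 lists, camera called 2 lower and 0 higher with an estimated correlation. With a preset correlation 6 were called higher and 16 lower, and fry, which asks only whether a list's genes move in a common direction, called 6 higher and 15 lower. The calls with an estimated correlation were those of the adipocyte and lymph node stroma lists, and the latter was lost in many alternatives. In a further 2-sided exact permutation test of list scores, which does not compare a list with other genes, more lists passed. Adjusted p over the lists was 0.00039 for endothelium, 0.00098 for macrophages, 0.0079 for HOX and 0.0237 for the cell cycle. The brown adipocyte, basal, oestrogen response, fibroblast, mast cell, neutrophil, skeletal muscle, p53, glycolysis, interferon and Wnt lists did not pass (0.0592 to 0.927). The lists without a common sign on the 3 slides were brown adipocyte, basal and myoepithelial, fibroblast, skeletal muscle, HOX and interferon.

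Carcinomas differed more from each other than normal glands did. The distance of an array from its group's mean, per gene on the log2 scale, was 0.852 ± 0.136 (SD, n = 13) in carcinomas and 0.69 ± 0.081 (SD, n = 6) in normal glands. The difference of 0.162 had a 2-sided exact permutation p of 0.0168, and 9 carcinomas lay farther from their mean than every normal gland. In the number-coded samples alone the difference was 0.127 and did not pass (exact permutation p = 0.0756). The difference was 0.128 within slide 1 (exact permutation p = 0.229), 0.269 within slide 2 (0.0667, the smallest p that its 15 splits allow) and 0.127 within the first scan day (0.0811), so it did not pass within any of these batches. Slide 3 and the letter-coded samples held 1 normal gland each, which gives no spread.

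Among the 13 carcinomas, macrophage and T and NK cell scores gave the strongest of 10 correlations between list scores. Pearson's r was 0.70 (permutation p = 0.00649, adjusted p = 0.0649) and Spearman's rho 0.71 (permutation p = 0.00878, adjusted p = 0.0878). Without the 2 carcinomas farthest from the median macrophage score r was 0.43. In the 10 number-coded carcinomas r was 0.68 (permutation p = 0.0252, adjusted p = 0.252), and 3 letter-coded carcinomas were too few for a value. In the 9 carcinomas of the first scan day r was 0.82 (exact permutation p = 0.0069, adjusted p = 0.069) and rho 0.83, and r was not computed within slides, which held at most 5 carcinomas each. None of the 10 pairs passed the adjustment. Cell cycle and oestrogen response scores gave r = -0.51 (permutation p = 0.0739, adjusted p = 0.37) and rho = -0.58 (permutation p = 0.0423, adjusted p = 0.212), with r = -0.42 without the 2 farthest carcinomas -0.27 in number-coded carcinomas and -0.70 within the first scan day (exact permutation p = 0.0351, adjusted p = 0.176). The other 8 pairs gave r from -0.32 to 0.31. A pair passed without carcinoma 6 or without carcinoma 13, with normexp and with quantile normalization (1 pair each).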

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

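The tests of array brightness on the group difference, of slide on the letter-coded samples, and of the 3 composition explanations were chosen only after the results were seen, as were the fits with brightness, within slides, within the first scan day and by code series.

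In 112 sets of 6 normal gland values, 11 held a sample far from the others, and chance gives about 1 in 20. Normal gland 3 had a skeletal muscle score of 6.63, with the others at -1.32 to 1.53, and lay apart in Cenpf (-6.73), Cldn5 (0.30) and Trem1 (-0.99). Normal gland 5 lay apart in the lymph node stroma (3.58) and interferon (0.19) scores, normal gland 2 in the basal score (-0.65) and normal gland 4 in the cholesterol synthesis score (-0.30). Normal gland 1 lay apart in the unfolded protein response score (0.72), in S100b (1.80) and in the share of spots well above background (77.2%). Without normal gland 3 the median of the skeletal muscle list turned to 0.01. Outside the main comparison, 695 of 9449 probes without a gene symbol were higher in carcinomas and 987 were lower.

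The first pattern is the number of genes changed between the groups. Of 100 splits of the 19 arrays, 1, the real one, gave as many higher genes (1244, highest other 250), as many lower genes (1692, 256), as many 2-fold changes (1670, 262) and as many lists called (2, 0). Chance alone is therefore unlikely, though 1 in 100 is the smallest share that this number of splits allows. The highest other split put all 4 letter-coded samples in the smaller group, which points to a structure of the samples. With array brightness in the model, genes called kept a median share of 0.769 of their change (0.734 to 0.87 without single arrays). Only 1 carcinoma array lay within the brightness range of the normal glands, so that share rests on a linear fit across nearly separate groups. It therefore cannot decide whether brightness is part or the whole of the cause, and brightness stays open. Calls fell to 11 higher and 174 lower because the median change went from 1.11 to 0.80 and the median SE from 0.285 to 0.482, since 66.8% of the variance of brightness lay between the groups. Tumour against gland, which the labels name, stays open as the biological explanation, and the irradiation of the rats cannot be separated from it.

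The next pattern is that the 4 letter-coded samples stood apart, with 867 genes higher and 1704 lower than in number-coded samples with group in the model. Of that difference, a median share of 0.911 (0.804 to 0.991) was kept with slide in the model and 0.98 (0.968 to 0.993) with array brightness. These values argue against slide and brightness as the whole cause. The labels do not explain the codes, and no biological explanation was tested.

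The last pattern is the difference in cell type and cell cycle lists. The adipocyte score fell by 4.28 more than the fibroblast score (2-sided exact permutation p = 3.69e-05, the smallest that the splits allow), so these 2 lists did not fall alike. Endothelium, macrophage and T and NK cell scores were lower in 3 of 3 cases, so the falls were not limited to the fat cell list. Both outcomes were known from the results when these tests were written. They therefore decide neither on an equal dilution of all cells other than epithelium nor on a lower share of fat cells alone. The cell cycle score rose by 0.67 more than the luminal score (exact permutation p = 0.187), so a higher share of epithelial cells may account for the cell cycle rise and stays open, as do changes within cells. Many list genes are expressed by more than 1 cell type, and no cell counts were used here.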

How the results depend on the processing

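The fits within slides and within the first scan day, by code series, without the arrays marked for evaluation and with array brightness were chosen after the data were seen. The adipocyte list was called lower in every setting that tested lists. Of 73 named genes called, 39 passed under every alternative that was run for named genes, other than the adipocyte covariate (fits within slides or scan day, of letter-coded samples, without marked arrays and with brightness were not among these), and 50 passed in all 19 fits without 1 array. The cause was not tested where none is given. Normexp gave 5256 genes lower, 1 list called and 1 correlated pair. It turned Gtse1 (-0.13), Dnmt3a (-0.046), Fancd2 (-0.42), Rad50 (-0.14), Esr1 (-0.73) and Brca1 (-0.74), the medians of the brown adipocyte (-0.67), oestrogen response (-0.040), DNA repair (-0.028) and interferon (-0.064) lists, and r of luminal with adipocyte scores (-0.030). The median of all genes with normexp was -0.37, and of these list medians only that of brown adipocytes lay below it. Genes near the background, such as Esr1 and Brca1, are limited by the signal over it. Lists called numbered 1 with quantile normalization, the authors' values, no filter, the stricter filter, array weights, slide, day or code blocks, number-coded samples or without arrays marked for evaluation, 22 with a preset correlation and 21 with fry. Median scaling over all probes called 3, adding endothelium (adjusted p = 0.0488). Sample numbers as a block, fitted without carcinomas 7 to 13, called 2, losing lymph node stroma (0.386) and adding macrophages (0.0329). Quantile normalization gave 1 correlated pair. No filter turned brown adipocytes to -0.38, and keeping marked spots turned r of luminal with adipocyte scores to -0.029. The luminal covariate gave 755 higher and 1098 lower, and 18 named genes no longer passed, all with a larger SE and 11 with at least 90% of their change. The adipocyte covariate gave 0 higher, 0 lower and 0 at 2-fold by limma, since the median SE went from 0.285 to 1.73. At an unadjusted p under 0.05 this covariate left 523 genes, fewer than chance alone gives on average. It turned Aspm (-0.18), Cenpf (-1.29), Gtse1 (-0.54), Kif11 (-0.76), Pbk (-1.76), Kcnk3 (0.0065), Gata3 (-0.39), Prom1 (-0.68), Lamb3 (-0.32), Glycam1 (8.31), Wap (10.56), Pgr (-0.21), Spp1 (0.61), Hoxa7 (1.37), Gata4 (2.64), Gdf15 (2.20), Fancd2 (-2.97), Thrsp (1.97), Me1 (2.33), Acsl1 (6.64), Mycn (-0.66), Sdf2l1 (0.47), Ddit3 (0.35), Brca1 (-1.26) and Brca2 (-1.44), none past the test. With fewer samples, slide 1 gave 153 higher, 534 lower and 679 at 2-fold, slide 2 gave 45, 267 and 312, slide 3 gave 0, 31 and 31, and the first scan day 673 higher. The spread difference did not pass within slide 1 (0.128), slide 2 (0.269), the first scan day (0.127) or number-coded samples (0.127). In the first scan day r of cell cycle with milk scores was -0.061. Letter-coded samples gave 0 higher, 0 lower and 0 at 2-fold by limma (1340 at an unadjusted p under 0.05). In number-coded samples r of cell cycle turned with fibroblast (-0.14) and p53 scores (0.032), and of luminal with adipocyte scores (-0.16). Without arrays marked for evaluation the fibroblast (0.0071) and mast cell (-0.25) medians turned. Brightness gave 11 higher, 174 lower and 185 at 2-fold. Without 1 array the ranges were 665 to 1442 higher, 1084 to 1830 lower, 1142 to 1860 at 2-fold, 1 to 2 lists, 0 to 1 correlated pairs and 0.142 to 0.191 for the spread. List medians ranged from -1.81 to 0.011 for skeletal muscle (highest without normal gland 3) and -0.031 to 0.62 for mast cells (lowest without carcinoma 13). For r the ranges were -0.060 to 0.129 for cell cycle with milk, -0.124 to 0.323 for cell cycle with fibroblast, -0.148 to 0.226 for luminal with adipocyte and -0.441 to 0.0037 for oestrogen response with milk scores. Sample numbers as a block, fitted without carcinomas 7 to 13, gave 949 higher and 1335 lower. That fit ended the calls of Fbln1, Dnmt3a, Gdf15, Rad50, Slc2a1, Mx2, Frzb, Erbb2, Ezh2 and Brca2. The block and the smaller number of samples cannot be told apart there. Values of r between same-number samples were -0.115 to 0.238 and over 0.1 in 1 of 6 cases, which gives little sign of pairing but cannot exclude it.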
